A study of Homo sapiens with 24 samples.

How the data were processed

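RNA of SH-SY5Y cells, an established human neuroblastoma line, was sequenced in 24 libraries that the labels place in 8 groups of 3. Cells were harvested at 4 h untreated or with copper chloride, and at 24 h untreated or with dextran-catechin (DC), with TEPA, with interferon gamma (IFN), or with DC or TEPA together with IFN. DC and TEPA are copper chelators. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a stranded mRNA kit. Doses are not in the labels, and the labels do not say whether the 3 libraries of a group come from independent cultures.

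The deposited values are whole-number read counts per gene symbol for 26485 genes, without normalization. Per the submitters' processing notes the tools were STAR 2.5a and RSEM 1.2.31 with genome build hg38. The notes give neither the annotation release nor the strand setting of the counting, nor any filter. The deposited counts come as 1 table of all libraries and as 1 list per library, and for all 24 libraries the list equals its column of the table. Library totals run from 24569980 to 35372442 counts, and 6378 genes have 0 counts in every library. Because the strand setting is unknown, antisense genes were not named. Genes with near-identical copies (metallothioneins, HSPA1A, HLA genes and GOLGA8R) are reported as uncertain, since counting may divide reads among copies. Totals and the counting intervals of ratios cover counting error only. The 95% intervals of log2 fold changes come from the fit and include the spread between libraries.

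Gene symbols were matched to GENCODE 29 on GRCh38 for locations, transcript length and GC content, which succeeded for 23925 symbols (90.3%). Of the 14654 genes tested, 93.8% had a GC content.

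Computed from the counts with R 4.3.3: genes with too few counts were removed with filterByExpr of edgeR 4.0.16 (minimum count of 10), which left 14654 genes, and library sizes were scaled with TMM factors. A quasi-likelihood negative binomial model with 1 mean per group was fitted in edgeR to all 24 libraries, with 16 residual degrees of freedom and a common biological coefficient of variation of 0.207. Each comparison was a contrast of group means, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes carry the standard error (SE) of the fit. CPM, the count as a rate of the scaled library total, are given as mean ± SD of the 3 libraries of a group (n = 3). Where all 3 libraries of a group had 0 counts, the fold is a bound against a floor of 3 counts over the group. Where a group held 1 to 3 counts in total, the ratio is given with its 95% counting interval.

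The 10 comparisons were copper against the 4 h control; DC, TEPA and IFN against the 24 h control; DC with IFN and TEPA with IFN against IFN; TEPA against DC; the difference in the DC and in the TEPA effect with and without IFN (interactions); and the 24 h against the 4 h control. Overlaps of called genes were set against the number expected from the sizes of both lists with Fisher's exact test. That test treats genes as independent and equally easy to call, which they are not. Its p therefore does not by itself measure a shared response. Because DC and TEPA share their control libraries, the correlation of their fold changes was set against 20 simulations with no treatment effect.

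Gene lists, 41 in number, cover copper and zinc handling, stress responses, interferon and antigen presentation, checkpoint ligands, metabolism, cell cycle, neuroblastoma identity, markers of other cell types and signs of RNA quality. Of these, 38 had at least 5 tested members and went through camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists within a comparison. Unless another test is named, the adjusted p of a list is that of camera. The call with a correlation estimated from the data stands beside many of the list calls. The self-contained test fry was run too but is given only as a total, with 47 of 97 list calls kept. A list call printed here may not pass it. For each list the members past the threshold over all genes are counted, with the count adjusted over the list alone.

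Genes are named by a rule. In each comparison these are the 8 with the largest rise and the 8 with the largest fall (5 and 5 for interactions and for TEPA against DC) among called genes with a mean of at least 1 CPM, a named coding-style symbol and no overlap between the 3 and 3 libraries, which chance gives in 10% of genes. Up to 4 called members of each list described, or the 2 most abundant where none is called, are also named, as are CD274, STAT3, IRF1, EGFR, SLC31A1, MT2A, MT1X, HSPA1A, HMOX1 and TFRC whatever their values. From this pool the text gives the genes that stand for their group. Some genes of the pool are not reported here. Groups, comparisons, lists, this rule and the alternatives were fixed before the data were examined, except where the text says otherwise.

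Alternatives were median-of-ratios and upper-quartile factors, no filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom, the libraries of the comparison alone, the replicate number as a block, a log2 fold change of at least 1 in size, Bonferroni adjustment, and each library of a comparison left out in turn. Added after seeing the data were a correction that removes each library's smooth trend against GC content (13739 genes), the same with the replicate block, the replicate block in the libraries of the comparison alone, and the 4 h groups without both libraries numbered 1. The smooth GC trend was not centred. The correction therefore also takes off each library's mean deviation over genes, on top of the TMM factors. The numbers 1 to 3 were taken as labels that could pair libraries across groups, and within-group deviations were correlated to see whether they do. Numbers are said to pair 2 groups where all 3 correlations of equal numbers passed a small positive cutoff. TEPA against DC (0.12, 0.76 and 0.52) met it, and TEPA on top of IFN (0.07, 0.54 and 0.56) did not. In no comparison did every library correlate best with its own number, so shared cultures or batches are not shown.

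The code was tested on simulated data drawn from the means and sizes of the real libraries in which some genes were changed by a known fold. For copper, 66 of 100 genes changed 2-fold and 27 of 100 changed 1.5-fold were called, with 1 call among unchanged genes. For TEPA the figures were 74 and 40 with 4 such calls, for DC 64 and 26 with 8, and for IFN 75 and 33 with 5. The TEPA by IFN interaction recovered 33 and 9, and the DC by IFN interaction 46 and 12. A list of 28 genes raised 1.3-fold was called and 0 of the other lists were. In all these tests each gene was drawn independently and without a GC trend. They therefore cannot show how often correlated genes or GC trends give false calls of genes or lists in the real libraries. With a GC trend simulated and then corrected, calls among unchanged genes were 7 for copper, 7 for TEPA and 3 for IFN.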

Results

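Transcript levels were measured by RNA sequencing in SH-SY5Y neuroblastoma cells, in 8 groups of 3 libraries. The 4 h control libraries held 26850107 to 30373569 counts and the copper libraries 27198884 to 29621388. At 24 h the totals were 29583302 to 34922165 in the control, 27469521 to 33019188 with DC and 28082355 to 35372442 with TEPA. They were 27664340 to 31986212 with IFN, 24569980 to 32622130 with DC and IFN, and 28706719 to 31987565 with TEPA and IFN. Between 16168 and 17030 genes had at least 1 count in a library. The series set out to study copper in neuroblastoma cells, and the comparisons ask which transcripts respond to added copper, to 2 copper chelators and to IFN, and whether a chelator acts differently when IFN is present. CD274, which encodes the immune checkpoint ligand PD-L1, lies on chromosome 9 from 5450503 to 5470566 (GRCh38).

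Libraries of the same group differed along a trend with GC content. The GC difference of a library is the median log2 level, relative to all libraries, of genes with a GC fraction above 0.6 minus that of genes under 0.4. It was -1.32 in control library 1 and -0.645 in copper library 1 at 4 h, against 0.653 to 1.38 in the other 4 libraries of that time. At 24 h its group means were -0.70 ± 0.31 in the control, 0.46 ± 0.53 with IFN and -0.39 ± 0.89 with TEPA (SD, n = 3). Fits with this trend removed are given beside many of the calls and counts that they change. Of 97 list calls 19 were lost in those fits and 15 others gained.

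**Figure D1:**
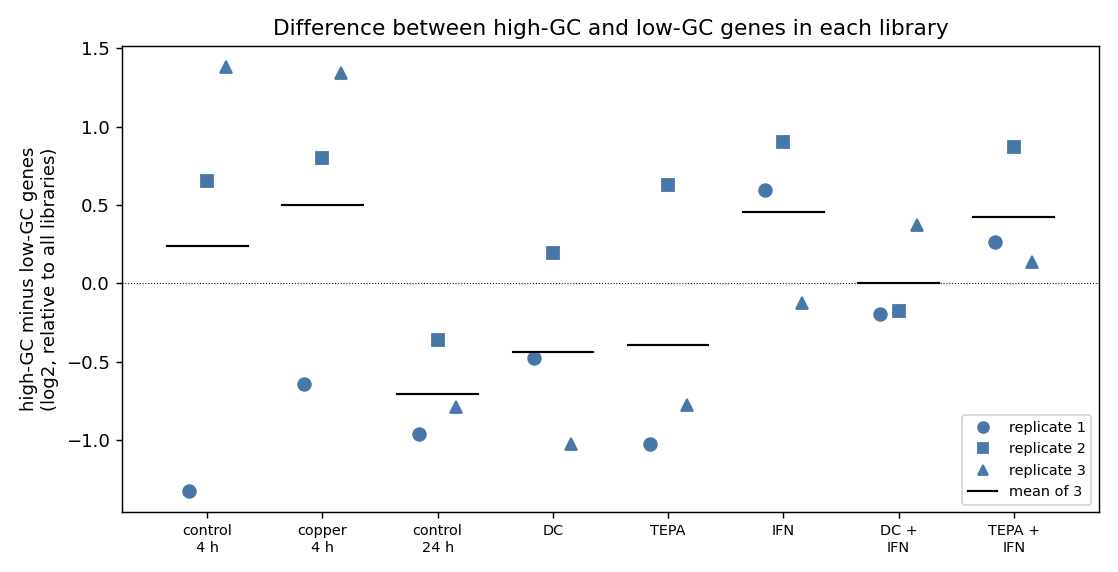
Log2 difference between the medians of genes of high and low GC content relative to all libraries (y axis) in each of the 24 libraries by group (x axis), with the mean of 3. The control library numbered 1 at 4 h sits at -1.32, and the spread within groups reaches an SD of 1.4.

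Copper at 4 h raised metallothioneins, small proteins that bind copper and zinc. MT1X went from 0.947 ± 0.651 to 50.7 ± 30.3 CPM (SD, n = 3), a log2 fold change of 5.71 (SE 0.63), and MT2A (chromosome 16, 56608199 to 56609497) had 5.28 (SE 0.53). Of 7 tested metallothioneins and MTF1 targets, 6 rose and 0 fell (6 and 1 adjusted over the list alone; adjusted p = 4.61e-20 for the list). SLC30A1, the zinc exporter of the plasma membrane (chromosome 1, 211571568 to 211578742), rose by 2.56 (SE 0.18), from 26.7 ± 5.46 to 157 ± 33.4 CPM. Metallothionein genes are near-identical, so the share of each is uncertain.

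Targets of ATF4, the transcription factor of the integrated stress response, rose with copper in 28 of 30 tested members (29 adjusted over the list alone; adjusted p = 1.92e-72). Among them CHAC1, which degrades glutathione, had a log2 fold change of 4.84 (SE 0.72), STC2 4.52 (SE 0.18), DDIT4, an inhibitor of mTORC1, 4.41 (SE 0.29) and SESN2 3.87 (SE 0.36). INHBE rose by 5.70 (SE 0.45) and ULBP1, a ligand of the natural killer receptor NKG2D, by 4.92 (SE 0.32). Of 27 NRF2 and oxidative stress genes, 8 rose (9 adjusted over the list alone; adjusted p = 1.53e-05, and 0.00445 with an estimated correlation). Heme oxygenase HMOX1 led them at 4.28 (SE 0.40), from 1.46 ± 0.52 to 28.5 ± 6.23 CPM, with the cystine importer SLC7A11 at 3.59 (SE 0.23), GCLM at 1.03 and TXNRD1 at 0.81. Immediate early genes rose in 12 of 30 cases and fell in 2 (18 and 2 adjusted over the list alone; adjusted p = 5.68e-14, and 0.0443 with an estimated correlation), among them ATF3 (3.30), JUN (1.42), IER2 (1.37) and DUSP5 (1.37).

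Several abundant genes fell with copper. HSPA8, the constitutive HSC70 chaperone (chromosome 11, 123057489 to 123063230), fell by 1.74 on the log2 scale (SE 0.17) and HSPA2 by 1.65 (SE 0.22), while HSPA1A had -0.68 (SE 0.22, adjusted p = 0.0853 in edgeR, and 0.0352 with GC trends removed). The heat shock list as a whole had 2 members up and 4 down of 24 (2 and 6 adjusted over the list alone) and was not called (adjusted p = 0.0669). GPRC5B (-1.25), SDPR (-1.57) and C17orf67 (-1.59) were also lower. Adrenergic neuroblastoma identity genes fell in 5 of 30 cases (8 adjusted over the list alone; adjusted p = 0.00373, and 0.0133 with an estimated correlation). SIX3 was at -0.87, HAND1 at -0.76 and the dopamine synthesis enzyme DDC at -0.52. Without copper library 1 this list was not called (adjusted p = 0.0519), nor with GC trends removed (median -0.20, adjusted p = 0.147). Of 25 cholesterol synthesis genes 4 fell (1 up and 7 down adjusted over the list alone), and the list was not called (adjusted p = 0.0663; 0.0352 with GC trends removed). Mitosis genes fell in 8 of 34 cases (14 adjusted over the list alone), such as DLGAP5 (-0.71) and CENPA (-0.39), and DNA replication genes in 7 of 40 (9 adjusted over the list alone), such as FEN1 (-0.72) and UNG (-0.54). Both lists passed camera (adjusted p = 5.13e-08 and 0.00121) but not with an estimated correlation (adjusted p = 0.154 and 0.493).

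CD274 was at 3.79 ± 1.12 CPM with copper and 2.17 ± 0.344 CPM in the 4 h control (SD, n = 3), a log2 fold change of 0.81 (SE 0.31) that did not pass in edgeR (adjusted p = 0.165). Over the alternatives the adjusted p ran from 0.0161 to 0.52, under 0.05 only with a replicate block combined either with the 6 libraries alone or with GC correction. None of the 15 checkpoint ligands was called, nor any of 21 MHC class I presentation genes, each also 0 adjusted over the list alone. Of 36 IFN gamma response genes 1 fell (1 adjusted over the list alone). Of 21 copper transport genes 2 rose (2 adjusted over the list alone), PRNP (1.39, SE 0.19) and COX19 (0.66, SE 0.12). The copper importer SLC31A1 had -0.21 (SE 0.09, adjusted p = 0.252; 0.00156 with GC trends removed and under 0.05 without control library 3 or copper library 1, in a range of 0.00156 to 0.963 over the alternatives). STAT3 (0.12), IRF1 (-0.04), EGFR (-0.14) and TFRC (-0.17) were not called. Among markers of other cells, PMP22 of Schwann cells fell (-0.71, SE 0.07; 1 of 5), and 0 of 10 fibroblast and endothelium, 0 of 2 epithelium and 0 of 3 leukocyte markers were called.

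In edgeR copper changed 857 of 14654 genes, 388 higher and 469 lower, of which 127 changed at least 2-fold (111 higher, 16 lower). With the 6 libraries of the comparison alone 61 genes were called, and in that fit MT1X, MT2A, CHAC1, PRNP, SIX3, FEN1 and DLGAP5 were no longer called. With GC trends removed 3003 genes were called (1248 higher, 1755 lower). By the rule on correlations the replicate numbers pair these libraries (0.87, 0.35 and 0.82), though not every library correlated best with its own number. With a replicate block 1100 genes were called. The fall of ACSL5, at least 3.06-fold against a copper group at 0 counts, and that of APLN (-1.72) each lost their call in 5 of the 6 fits without 1 library (adjusted p up to 0.105 and 0.116).

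**Figure D2:**
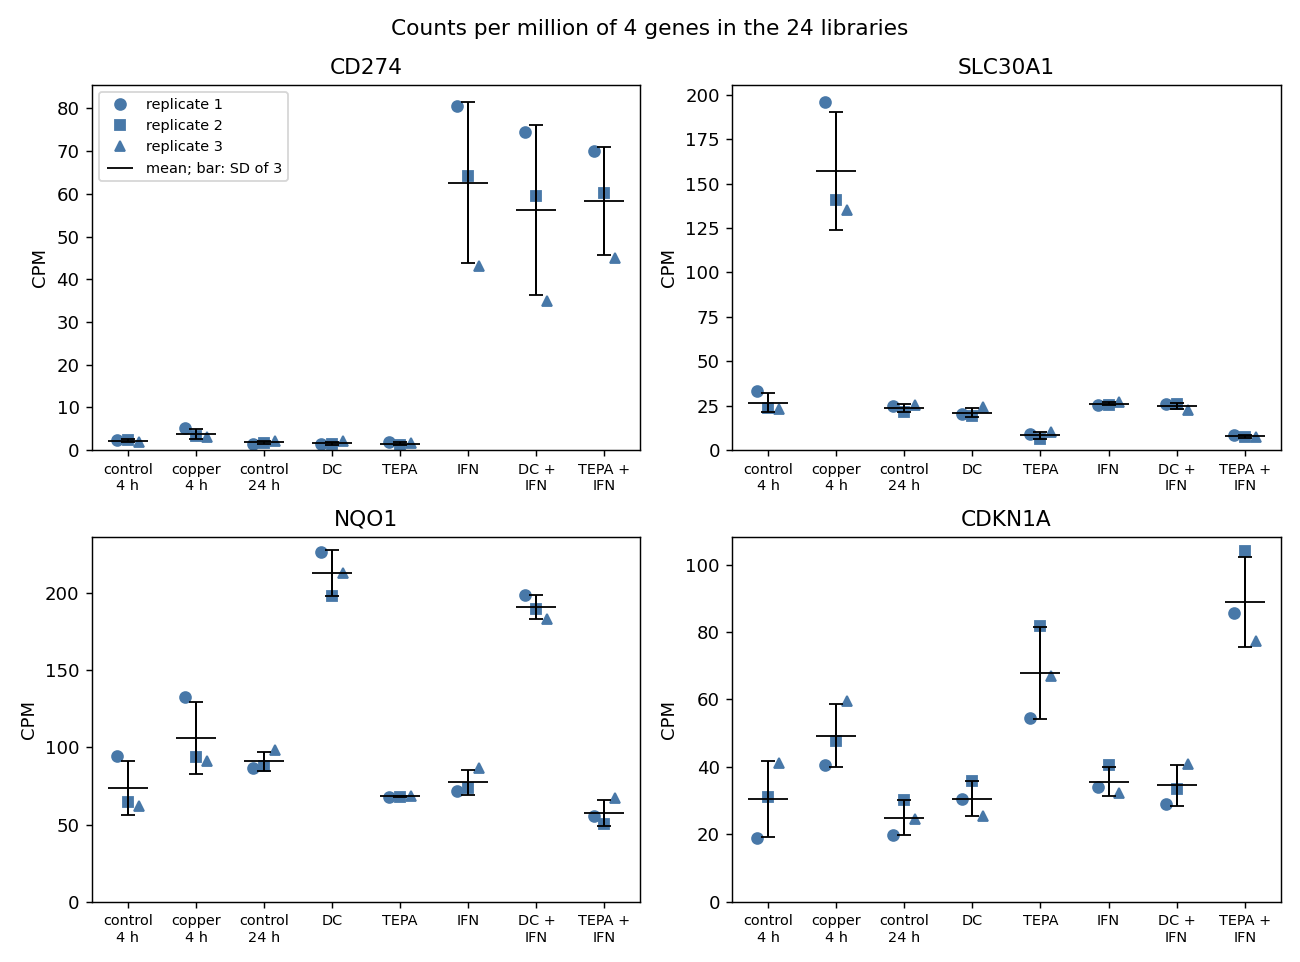
CPM of CD274, SLC30A1, NQO1 and CDKN1A (y axes, which differ) in each library by group (x axis), with mean and SD of 3 libraries. CD274 averages 62.6 CPM with IFN against 1.78 in the 24 h control, SLC30A1 157 with copper, NQO1 213 with DC and CDKN1A 67.8 with TEPA.

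DC for 24 h raised NQO1, a quinone reductase under NRF2 control (chromosome 16, 69706996 to 69726951), from 91.1 ± 6.15 to 213 ± 14.7 CPM (SD, n = 3), a log2 fold change of 1.22 (SE 0.15). FTH1, the heavy chain of the iron store ferritin (chromosome 11, 61959718 to 61967660), rose by 0.48 (SE 0.07). They are the called members of the NRF2 and oxidative stress list (2 of 27 higher; 7 adjusted over the list alone; adjusted p = 1.51e-26 for the list, and 5.49e-07 with an estimated correlation). FTH1 was also the called member of the iron homeostasis list (1 of 18; 1 adjusted over the list alone; adjusted p = 4.12e-05, and 0.00264 with an estimated correlation). The autophagy and lysosome list was higher by camera with 0 of 31 members called, also adjusted over the list alone (adjusted p = 0.000266, and 0.0277 with an estimated correlation).

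CD274 was at 1.62 ± 0.376 CPM with DC and 1.78 ± 0.38 CPM without (log2 fold change -0.14, SE 0.33, adjusted p = 1 in edgeR). STAT3 (-0.04), IRF1 (-0.04), EGFR (-0.18), SLC31A1 (-0.08), MT2A (-0.12), HMOX1 (0.52) and TFRC (0.33) were not called either. No member was called, also adjusted over the list alone, among the 7 metallothioneins and MTF1 targets, 21 copper transport genes, 36 IFN gamma response genes, 21 MHC class I genes or 15 checkpoint ligands. The same holds for the 5 Schwann cell, 10 fibroblast and endothelium, 2 epithelium and 3 leukocyte markers. Camera with its preset correlation also called 4 lists higher and 2 lower without a called member. Those higher were ATF4 targets (adjusted p = 0.323 with an estimated correlation), cytosolic ribosomal proteins (0.706), ER chaperones (0.323) and Schwann cell markers (0.323), and those lower were mitosis (0.323) and DNA replication (0.706). Schwann cell markers lost their call with GC trends removed (adjusted p = 0.0783) and cytochrome c oxidase genes gained 1 (0.121 before, 0.00526 after). DNA replication was lost without DC library 1 or 3 and turned to the higher side without control library 2 (adjusted p up to 0.971).

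In edgeR 2 genes were called for DC, both higher; 135 had an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 2. In the 6 libraries of the comparison alone FTH1 lost its call (adjusted p = 0.157). With a replicate block in these libraries, which the numbers pair, 6 genes were called, FTH1 among them (adjusted p = 0.00605). With GC trends removed 7 genes were called, all higher, which were NQO1, FTH1, ME1, SLC7A11, SQSTM1, TFRC and TXNRD1 (chosen after their values were seen).

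TEPA for 24 h raised p53 targets. CDKN1A, the cell cycle inhibitor p21 (chromosome 6, 36676460 to 36687339), went from 24.9 ± 5.22 to 67.8 ± 13.7 CPM (SD, n = 3), a log2 fold change of 1.45 (SE 0.24). The death receptor FAS rose by 1.63 (SE 0.24), PHLDA3 by 1.69 (SE 0.25), and DDB2, a DNA damage recognition protein, by 1.32 (SE 0.19). Of 28 p53 targets 11 rose and 0 fell (19 and 0 adjusted over the list alone; adjusted p = 2.85e-31, and 4.29e-07 with an estimated correlation), with a list median of 0.80. Also higher were EDA2R (1.36, SE 0.19) and the sodium channel subunit SCN4B (1.77, SE 0.29).

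Metal handling genes moved in both directions with TEPA. SLC30A1 fell from 23.8 ± 2.18 to 8.39 ± 1.96 CPM (log2 fold change -1.5, SE 0.17), while the zinc importer SLC39A10 rose from 152 ± 13.4 to 360 ± 64.5 CPM (1.25, SE 0.18). MT1F fell from 14 counts to 1 in total (ratio 0.0674, 95% counting interval 0.00159 to 0.443). It lost its call in DESeq2 (adjusted p = 0.106), in limma-voom (0.0673) and without any single library except TEPA library 2 (up to 0.175). MT2A (-1.37, SE 0.70) and MT1X (-1.98, SE 1.07) were not called. The list of metallothioneins and MTF1 targets had 1 member up and 2 down of 7 (1 and 2 adjusted over the list alone) and passed camera (adjusted p = 0.0332) but not with an estimated correlation (adjusted p = 0.124) or with GC trends removed (0.0731). SLC31A1 had 0.19 (SE 0.09, adjusted p = 0.555; 0.000679 with GC trends removed, in a range of 0.000679 to 0.721 over the alternatives), and 0 of 21 copper transport genes were called (0 up and 1 down adjusted over the list alone).

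Lipid synthesis genes were lower with TEPA. Of 25 cholesterol synthesis genes 3 fell (10 adjusted over the list alone; adjusted p = 1.53e-06, and 0.000368 with an estimated correlation). They included FDFT1 (-0.39) and ACAT2 (-0.36), each of which lost its call in at least 4 of 6 fits without 1 library (adjusted p up to 0.0787 and 0.091). Of 15 fatty acid synthesis genes 2 fell (3 adjusted over the list alone; adjusted p = 0.000899, and 0.00916 with an estimated correlation), the desaturase SCD (-0.45, SE 0.07) and ACACA (-0.35), the latter lost in 5 of 6 such fits (adjusted p up to 0.164). The transferrin receptor TFRC rose by 0.71 (SE 0.16, adjusted p = 0.0397), without its call in all such fits except that without TEPA library 2 (adjusted p 0.0688 to 0.106). IFRD1 (-1.23, SE 0.18), ANOS1 (-1.54, SE 0.25) and ANO4 (-1.31, SE 0.21) fell.

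Immune genes showed few calls with TEPA. CD274 was at 1.5 ± 0.364 CPM (log2 fold change -0.27, SE 0.33, adjusted p = 0.855 in edgeR), and STAT3 (0.17), IRF1 (0.02), EGFR (0.13) and HMOX1 (0.31) were not called. FGL1, a ligand of the checkpoint receptor LAG3, rose by 1.21 (SE 0.20), the only called member of 15 checkpoint ligands (1 adjusted over the list alone). None of 36 IFN gamma response genes (1 higher adjusted over the list alone) and none of 21 MHC class I genes (0) was called. The type I interferon list (0 of 31; 1 higher adjusted over the list alone) and the cytosolic ribosomal protein list (0 of 30; 0) were higher by camera, but not with an estimated correlation (adjusted p = 0.658 and 0.525). The former was not called with GC trends removed either (adjusted p = 0.0821). Of 10 fibroblast and endothelium markers ACTA2 rose (1.54, SE 0.30). Its call was lost without control library 1 or 3 or TEPA library 2 (adjusted p up to 0.097). ACTA2 (chromosome 10, 88935074 to 88991339) overlaps FAS (88990582 to 89015785), which lies on the other strand and also rose. With the strand setting unknown, the source of the ACTA2 reads is uncertain. Of the others, 0 of 5 Schwann cell, 2 epithelium and 3 leukocyte markers were called.

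In edgeR TEPA changed 155 genes, 76 higher and 79 lower, of which 34 changed at least 2-fold (22 higher, 12 lower). The count was 0 with the 6 libraries of the comparison alone (247 there with a replicate block, by whose numbers these libraries pair), 374 in DESeq2 and 1181 with GC trends removed. Without control library 1 it was 61, without control library 3 72, without TEPA library 1 82 and without TEPA library 3 63.

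**Figure D3:**
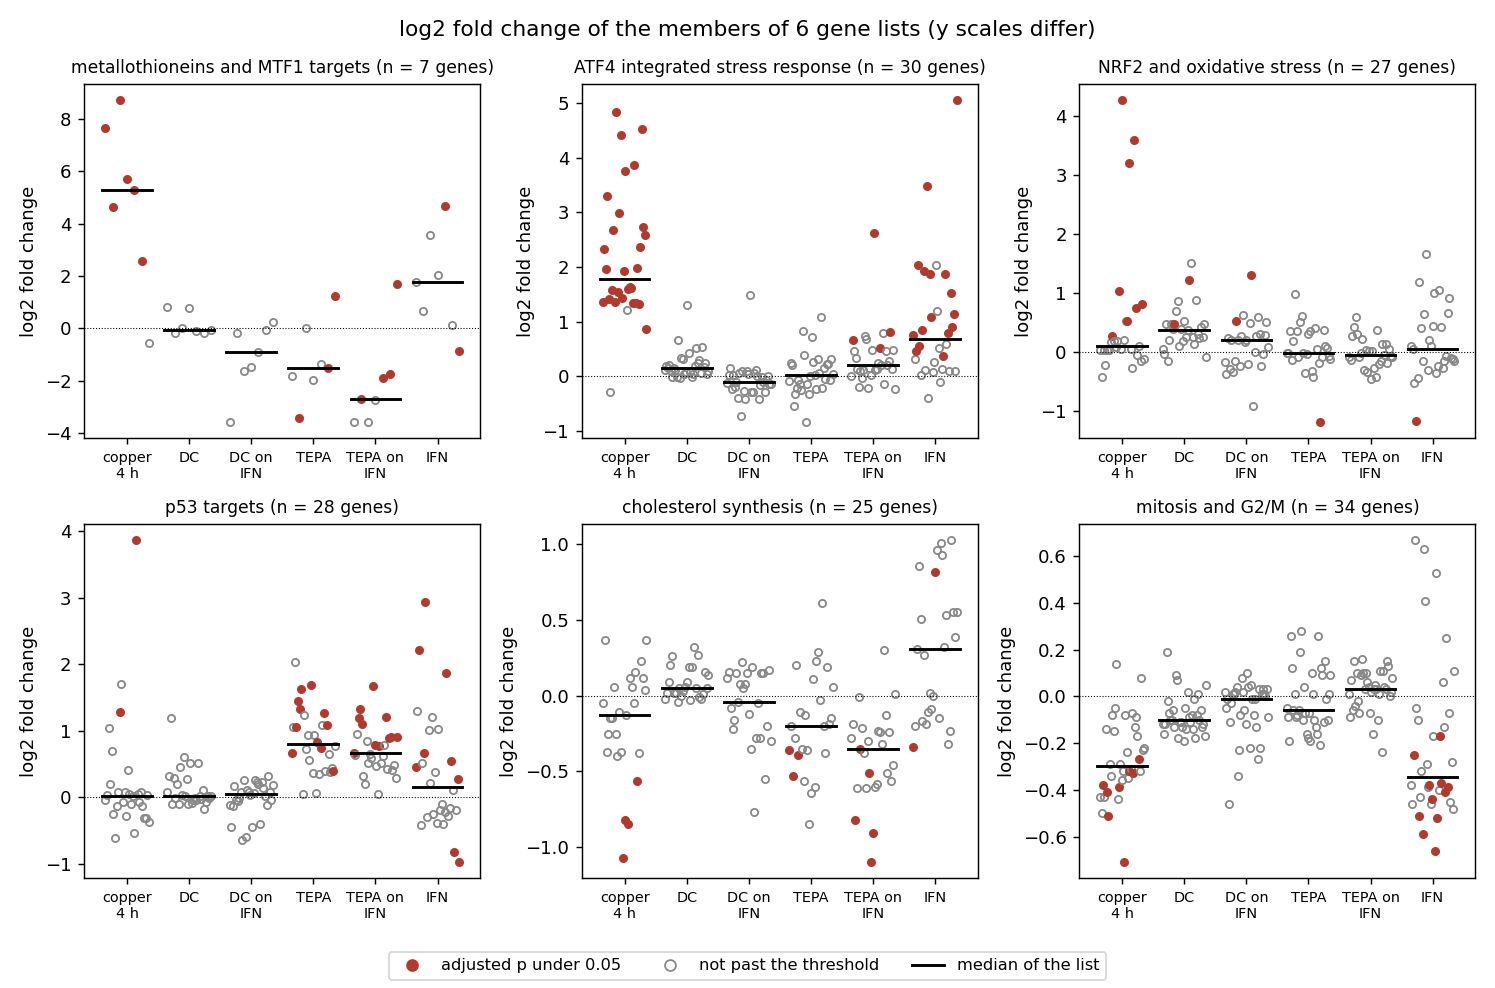
Log2 fold change (y axes, which differ) of each tested member of 6 gene lists in 6 comparisons (x axis), with the list median as a line and members with adjusted p under 0.05 filled; fits for genes at 0 counts in a group are not bounds. The p53 targets have medians of 0.80 with TEPA and 0.66 with TEPA on top of IFN, and the ATF4 list 1.79 with copper.

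IFN for 24 h raised CD274 from 1.78 ± 0.38 to 62.6 ± 18.9 CPM (SD, n = 3), a log2 fold change of 5.13 (SE 0.34, adjusted p = 5.31e-10 in edgeR). The transcription factor IRF1 (chromosome 5, 132481609 to 132490798) rose by 7.32 (SE 0.31) to 348 ± 116 CPM, STAT2 by 3.59 (SE 0.10) and STAT3 by 2.08 (SE 0.11). The IFN gamma response list had 35 of 36 members higher and the type I interferon signature 31 of 31 (35 and 31 adjusted over the list alone; adjusted p = 1.74e-64 and 6.91e-62, and 0.000126 and 7.88e-05 with an estimated correlation). OAS2 (12.05, SE 0.42), IFI27 (11.40, SE 0.53) and APOL1 (11.82, SE 0.29) were among them. Genes without counts in the 24 h control rose by at least 2600-fold (CXCL9), 642-fold (CASP1) and 550-fold (RTP4). IFITM1 went from 1 count to a ratio of 12000 (95% counting interval 2160 to 475000), MX2 from 1 count to 11300 (2020 to 445000) and IDO1, which degrades tryptophan, from 3 counts to 5240 (1790 to 25400).

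Antigen presentation rose with IFN. Of 21 MHC class I genes 18 rose (19 adjusted over the list alone; adjusted p = 1.34e-32, and 0.000126 with an estimated correlation). Among them were the peptide transporter TAP1 (10.65, SE 0.27), the proteasome subunit PSMB9 (11.11, SE 0.36) and HLA-B (10.73, SE 0.41), whose share is uncertain because HLA genes are near-identical in part. MHC class II genes rose in 12 of 14 cases (12 adjusted over the list alone; adjusted p = 5.36e-13, and 0.0216 with an estimated correlation). The class II activator CIITA was at least 150-fold higher, CD74 at a ratio of 867 from 1 count (155 to 34300) and IFI30 at 5.69 (SE 0.35). The median of this list was 6.62, or 4.07 with the 7 members at 0 counts in the control set to their bounds. Checkpoint ligands rose in 10 of 15 cases and fell in 2 (11 and 2 adjusted over the list alone; adjusted p = 4.27e-09, and 0.00143 with an estimated correlation). Among the risers were CEACAM1 (7.27), LGALS9 (7.18) and HLA-E (6.31). Cytokines and chemokines rose in 11 of 16 cases (12 adjusted over the list alone; adjusted p = 1.37e-12, and 0.000548 with an estimated correlation). Examples were CSF1 (5.58, SE 0.28), CXCL11 (ratio 1780 from 2 counts, 493 to 14700) and CXCL10 (1400 from 2 counts, 386 to 11500).

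Signalling and identity genes moved with IFN as well. Interferon signalling components rose in 10 of 20 cases (10 up and 1 down adjusted over the list alone; adjusted p = 1.04e-05, and 0.0476 with an estimated correlation), including the feedback inhibitors SOCS1 (6.19, SE 0.76) and SOCS3 (2.13, SE 0.19). Mesenchymal neuroblastoma identity genes rose in 7 of 23 cases (7 adjusted over the list alone; adjusted p = 0.0034, and 0.0482 with an estimated correlation), which included IRF1, IRF2 (1.93) and the matrix protein fibronectin FN1 (1.97, SE 0.08). ATF4 targets rose in 16 of 30 cases (17 adjusted over the list alone), led by the tryptophanyl-tRNA synthetase WARS (5.06, SE 0.18), CHAC1 (3.49) and ATF3 (2.04), but the list did not pass with an estimated correlation (adjusted p = 0.164). NF-kB targets rose in 6 of 16 (6 adjusted over the list alone), with the adhesion molecule ICAM1 at 7.30, and did not pass that way either (adjusted p = 0.0894), nor with GC trends removed (median 0.02, adjusted p = 0.12). Mitosis genes fell in 11 of 34 cases (1 up and 21 down adjusted over the list alone), with CCNB2 at -0.59 and DLGAP5 at -0.66, and again not with an estimated correlation (adjusted p = 0.269).

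Among metal genes, MT2A rose with IFN by 4.66 (SE 0.54), from 0.318 ± 0.103 to 8.16 ± 2.92 CPM, SLC39A10 fell by 0.86 on the log2 scale (SE 0.18) and MT1X had 2.05 (SE 0.71, adjusted p = 0.0502). The list of metallothioneins and MTF1 targets had 1 member up and 1 down of 7 (3 and 1 adjusted over the list alone; adjusted p = 0.167). Copper transport genes had 3 up and 1 down of 21 (4 and 2 adjusted over the list alone). The metal-responsive transcription factor MTF1 was at 0.45 (SE 0.09) and APP at 0.31 (SE 0.07). SLC31A1 had 0.08 (SE 0.09, adjusted p = 0.492; 0.14 and 0.00802 with GC trends removed) and ATOX1 (1.08) lost its call in 4 of 6 fits without 1 library (adjusted p up to 0.0976). TFRC fell by 0.69 (SE 0.16), and EGFR (0.16), HMOX1 (0.44) and HSPA1A (-0.04) were not called, though HSPA1A had -0.78 with GC trends removed (adjusted p = 0.0162). Lower with IFN were MEGF10 (-3.0, SE 0.39), XKRX (-2.21), the interleukin 6 receptor IL6R (-2.17, SE 0.32), CLSTN2 (-2.05, SE 0.19), MRAP2 (-2.03, SE 0.17) and MTURN (-1.97, SE 0.15). Markers of other cells were mixed, with ACTA2 (2.11) and PDGFRB (1.15) higher and COL1A2 (-0.82) lower of 10 fibroblast and endothelium markers. ACTA2 is uncertain, since it overlaps FAS, which rose as well. The others called were CD68, higher (3.34, SE 0.60; 1 of 3 leukocyte markers), ESRP1, lower (-2.75, SE 0.54; 1 of 2 epithelium markers), and PMP22, higher (0.23, SE 0.07; 1 of 5 Schwann cell markers). PDGFRB lost its call in 3 and PMP22 in 6 of 6 fits without 1 library (adjusted p up to 0.0834 and 0.166).

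In edgeR IFN changed 2761 genes, 1471 higher and 1290 lower, of which 948 changed at least 2-fold (740 higher, 208 lower). The share of called genes that were higher was 53.3%, but 27.8% with GC trends removed, where 5616 genes were called (1563 higher, 4053 lower). The control and IFN groups differ in that trend. The correction also takes off each library's mean deviation over genes, to which the strong rises with IFN contribute. How far each of these shifted the share was not tested. Several fold changes were smaller in that fit, though still called, as for SOCS1 (4.95), SOCS3 (1.32), CHAC1 (2.51), CSF1 (4.79), ICAM1 (6.68) and PDGFRB (0.47). Without control library 1 the count was 1821, without IFN library 1 1717 and without IFN library 2 1707, and it was 6703 with the 6 libraries alone.

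Against IFN alone, DC with IFN raised the same pair of genes as DC without IFN. NQO1 rose from 77.4 ± 7.97 to 191 ± 7.63 CPM (SD, n = 3), a log2 fold change of 1.3 (SE 0.15), and FTH1 rose by 0.52 (SE 0.07). Both genes called with DC were called here (0.000409 expected; Fisher's exact test across genes, p = 2.79e-08), though the genes are not independent replicates. Across all tested genes the DC fold changes without and with IFN did not go together (Pearson -0.331, Spearman -0.317). Those of TEPA without and with IFN had 0.298 and 0.43. Without GC correction the calls shared by DC without and with IFN were this pair of genes. With GC trends removed NQO1, FTH1, ME1, SQSTM1, TFRC and TXNRD1 were called, all higher, both without and with IFN. The correlations above are of fold changes without GC correction. The mean GC difference rose from -0.70 in the control to -0.44 with DC. It fell from 0.46 with IFN to 0 with DC and IFN, so the trend may enter the DC correlations. The NRF2 list had 2 of 27 members higher (9 adjusted over the list alone; adjusted p = 5.36e-09, and 0.000584 with an estimated correlation) and the iron list 1 of 18 (2 adjusted over the list alone; adjusted p = 0.0008, and 0.0127 with an estimated correlation). FN1 fell by 0.59 (SE 0.08), from 1130 ± 62.3 to 753 ± 62.8 CPM, and lost its call without DC with IFN library 2 (adjusted p = 0.109), without IFN library 2 (0.0839) and with GC trends removed (log2 fold change -0.64, adjusted p = 0.227). Over the alternatives its adjusted p ran from 1.05e-08 to 0.821.

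CD274 with DC and IFN was at 56.3 ± 19.9 CPM (log2 fold change against IFN -0.15, SE 0.27, 95% interval -0.72 to 0.42). STAT3 (-0.15), IRF1 (-0.33), EGFR (-0.20), SLC31A1 (0.06), MT2A (-0.89), MT1X (-1.47), HMOX1 (0.21) and TFRC (0.57, adjusted p = 0.95) were not called, but TFRC was with GC trends removed (0.52, adjusted p = 0.000132). Camera called 9 lists lower that did not pass with an estimated correlation. These were the type I interferon signature (0 of 31 called; adjusted p = 0.162), MHC class II (0 of 14; 0.217) and class I (0 of 21; 0.366), and the IFN gamma response (0 of 36; 0.376). They also were cytokines and chemokines (0 of 16; 0.158), metallothioneins and MTF1 targets (0 of 7; 0.0685), NF-kB targets (0 of 16; 0.217) and, with FN1 as the called member, mesenchymal identity (1 of 23; 0.216) and extracellular matrix (1 of 28; 0.265). The same holds for 3 lists called higher without a called member, which were cytochrome c oxidase (0.0685), ER chaperones (0.237) and autophagy and lysosome (0.162), the last with a median of 0.04 but a mean of -0.02. Adjusted over the list alone these lists gave the same counts. Of those lower, 4 were not called with GC trends removed, which were MHC class I (adjusted p = 0.302), NF-kB targets (0.189), mesenchymal identity (0.0855) and metallothioneins (0.137). No copper transport gene (21), checkpoint ligand (15) or marker of the 4 other cell types was called, also adjusted over the list alone.

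In edgeR 3 genes were called for DC on top of IFN, 2 higher and 1 lower; 336 had an unadjusted p under 0.05, DESeq2 called 6 and limma-voom 3. With the 6 libraries of the comparison alone only NQO1 was called, and with a replicate block in these libraries the count was 0, though the numbers do not pair them. With GC trends removed 7 genes were called, all higher, namely FTH1, ME1, NQO1, SQSTM1, TFRC, TXNRD1 and GCLM (chosen after their values were seen).

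TEPA on top of IFN raised p53 targets again. CDKN1A rose by 1.32 (SE 0.24) from 35.6 ± 4.27 to 88.9 ± 13.4 CPM (SD, n = 3), PHLDA3 by 1.67 (SE 0.25), SPATA18 by 1.21 (SE 0.15) and the antiproliferative gene BTG2 by 1.19 (SE 0.15). Of 28 p53 targets 11 rose (19 adjusted over the list alone; adjusted p = 9.63e-28, and 1e-06 with an estimated correlation), and 8 of these were also called with TEPA alone. EDA2R (1.22, SE 0.19) was higher as well. Of all genes, 94 were called with TEPA both without and with IFN, 46 higher in both and 48 lower in both (2.95 expected; Fisher's exact test across genes, p = 1.97e-126).

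SLC39A10 rose on top of IFN by 1.68 (SE 0.18) from 83.8 ± 11.8 to 268 ± 15.9 CPM, and SLC30A1 fell from 26.1 ± 1.01 to 7.75 ± 0.761 CPM (log2 fold change -1.75, SE 0.18). Metallothioneins and MTF1 targets had 1 member up and 3 down of 7 (1 and 6 adjusted over the list alone; adjusted p = 3.28e-05, and 0.00371 with an estimated correlation). MT2A (-1.92, SE 0.45) was lost in 5 of 6 fits without 1 library (adjusted p up to 0.177). TFRC rose by 0.81 (SE 0.16). Cholesterol synthesis genes fell in 5 of 25 cases (14 adjusted over the list alone; adjusted p = 2.57e-10, and 2.27e-05 with an estimated correlation). Among them were INSIG1 (-1.10, SE 0.21) and IDI1 (-0.51, SE 0.11), the latter lost in 3 of 6 fits without 1 library (adjusted p up to 0.0706). Fatty acid synthesis genes fell in 2 of 15 cases (5 adjusted over the list alone; adjusted p = 4.91e-06, and 0.000805 with an estimated correlation), namely SCD (-0.62, SE 0.07) and ACACA (-0.37, SE 0.08). Cytochrome c oxidase genes, of which 1 of 29 was called (COX15, 0.34; 2 adjusted over the list alone), passed camera both ways (adjusted p = 0.000624, and 0.00604 with an estimated correlation). LYPD1 (-2.26, SE 0.41), SYT2 (-1.52, SE 0.26) and CSPG5 (-1.31, SE 0.23) fell.

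CD274 with TEPA and IFN was at 58.4 ± 12.6 CPM (log2 fold change against IFN -0.1, SE 0.27, 95% interval -0.67 to 0.47). STAT3 (-0.05), IRF1 (0.02), EGFR (0.09), SLC31A1 (0.26, adjusted p = 0.194), HSPA1A (-0.53) and HMOX1 (-0.46) were not called, but SLC31A1 was with GC trends removed (0.29, adjusted p = 4.25e-05). FGL1 rose by 1.08 (SE 0.20), 1 of 15 checkpoint ligands (1 adjusted over the list alone), and COX19 was 1 of 21 copper transport genes called (0.47; 1 adjusted over the list alone), though in 0 of 6 fits without 1 library. The type I interferon signature (2 of 31 lower; 7 adjusted over the list alone) and the IFN gamma response (2 of 36 lower; 2) passed camera (adjusted p = 0.000149 each) but not with an estimated correlation (adjusted p = 0.293 and 0.308). MX1 (-1.26), SAMD9 (-0.64), STAT2 (-0.39) and SP140L (-0.49) were the called members, and each lost its call in at least 4 of 6 fits without 1 library (adjusted p up to 0.253, 0.164, 0.147 and 0.0726). No MHC class I gene (21) was called.

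Other lists called on top of IFN by the preset correlation did not pass with an estimated one. Higher were ATF4 targets (4 of 30, such as PSPH at 0.52; adjusted p = 0.167), cytosolic ribosomal proteins (0 of 30; 0.308) and ribosome biogenesis (0 of 26; 0.05). Lower were heat shock (1 of 24; 0.308), hypoxia (1 of 31; 0.0554), neuronal differentiation (2 of 26, such as GAP43 at -0.39; 0.0554) and Schwann cell markers (1 of 5, PMP22 at -0.27; 0.234), with PMP22 called in 0 of 6 fits without 1 library. These markers were not called with GC trends removed (adjusted p = 0.183). Adjusted over the list alone these counts were 7, 0, 0, 4, 2, 3 and 2. Of the other markers 0 of 10 fibroblast and endothelium genes (1 adjusted over the list alone), 0 of 2 epithelium and 0 of 3 leukocyte genes were called.

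In edgeR TEPA on top of IFN changed 279 genes, 111 higher and 168 lower. With GC trends removed 1811 genes were called and the balance turned (1016 higher, 795 lower), DESeq2 called 583, and the 6 libraries alone gave 121. Without IFN library 1 the count was 169, without IFN library 2 175, and without TEPA with IFN library 1 or 2 it was 130 or 124.

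TEPA and DC, both chelators used for 24 h at doses the labels do not give, were compared directly. With TEPA, p53 targets were higher than with DC in 12 of 28 cases (19 adjusted over the list alone; adjusted p = 3.92e-29, and 7.1e-07 with an estimated correlation), such as FAS (1.44, SE 0.24), PHLDA3 (1.42), DDB2 (1.33) and SPATA18 (1.26). NRF2 genes were lower with TEPA in 5 of 27 cases (8 adjusted over the list alone; adjusted p = 2.86e-09, and 0.000198 with an estimated correlation). SLC7A11 was at -2.07 (SE 0.22), NQO1 at -1.64 (SE 0.15; 68.3 ± 0.302 against 213 ± 14.7 CPM, SD, n = 3) and FTH1 at -0.55 (SE 0.07). SLC30A1 was lower (-1.33, SE 0.17), and SLC39A10 (1.31, SE 0.18), SCN4B (1.59) and FGL1 (1.18, SE 0.20) were higher, SCN4B without its call in the absence of DC library 1 (adjusted p = 0.0577). Cholesterol synthesis was lower in 4 of 25 (9 adjusted over the list alone; adjusted p = 4.53e-09, and 5.82e-05 with an estimated correlation). Fatty acid synthesis was lower in 1 of 15 (SCD, -0.44; 4 adjusted over the list alone; adjusted p = 4.44e-05, and 0.00155 with an estimated correlation).

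CD274 did not differ detectably between TEPA and DC (-0.13, SE 0.33), nor did STAT3 (0.21), IRF1 (0.06), SLC31A1 (0.26), HMOX1 (-0.21) or TFRC (0.38). SLC31A1 and TFRC were called with GC trends removed (adjusted p = 0.00014 and 0.000188, with the same fold changes). EGFR had 0.31 (SE 0.08, adjusted p = 0.0706; 0.00521 to 0.313 over the alternatives, among them 0.00642 with GC trends removed). Called were FGL1 of 15 checkpoint ligands and ACTA2 (1.59) of 10 fibroblast and endothelium markers (1 each adjusted over the list alone). ACTA2 lost its call without DC library 1 or 3 (adjusted p up to 0.069). It overlaps FAS, which was higher too, and is uncertain. Of the others, 0 of 36 IFN gamma response, 21 MHC class I, 5 Schwann cell, 2 epithelium and 3 leukocyte genes were called. Of 21 copper transport genes 0 were called (0 up and 1 down adjusted over the list alone). Lists called only with the preset correlation were metallothioneins and MTF1 targets (1 up, 2 down of 7; adjusted p = 0.0541 with an estimated correlation), ER chaperones (0.11), ribosomal proteins (0.583), ATF4 targets (0.583), histone transcripts (0.279), heat shock (0.583) and the type I signature (0.583). Histone transcripts (0.255) and the type I signature (0.0954) were not called with GC trends removed.

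In edgeR 185 genes differed between TEPA and DC, 86 higher and 99 lower with TEPA. The count was 2 with the 6 libraries alone, SLC7A11 and NQO1 (406 there with a replicate block, by whose numbers they pair), 434 in DESeq2 and 1361 with GC trends removed. Without DC library 1 it was 75, without DC library 3 106, without TEPA library 1 113 and without TEPA library 3 85.

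Whether a chelator acted differently with IFN was tested as an interaction. For CD274 the TEPA effect with IFN minus that without was 0.17 (SE 0.42, 95% interval -0.72 to 1.06) and the DC effect difference -0.01 (SE 0.44, -0.93 to 0.90). SLC30A1 had -0.25 (SE 0.24) for TEPA and 0.09 (SE 0.24) for DC, and SLC39A10 0.43 (SE 0.25) and 0.32 (SE 0.25), all with adjusted p above 0.05 in edgeR. For DC edgeR called 0 genes at adjusted p under 0.05, 142 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0. For TEPA edgeR called 0, 205 had an unadjusted p under 0.05, DESeq2 and limma-voom called 0, and with GC trends removed edgeR called 6, SLC39A10 among them (0.42, adjusted p = 0.0222).

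With TEPA, 3 lists differed by IFN both ways of treating the correlation, each without a called member. They were the type I signature (median -0.50; adjusted p = 1.04e-14, and 0.0431 with an estimated correlation), hypoxia (median -0.13; 0.000831 and 0.0431) and adrenergic identity (median -0.13; 0.0118 and 0.0431), the last not called without the low-count filter (0.0889) or with GC trends removed (median -0.03, adjusted p = 0.0941). The type I list had a median of 0.25 with TEPA alone and -0.36 on top of IFN. The latter uses the same IFN libraries as DC on top of IFN (-0.32). A high level in those libraries could enter this difference. Lists called with the preset correlation alone for the TEPA interaction were, on the higher side, ATF4 targets (0.0645 with an estimated correlation), mitosis (0.656) and immediate early genes (0.673). On the lower side they were the IFN gamma response (0.162), Schwann cell markers (0.0645), MHC class I (0.193) and class II (0.32), cytokines (0.193), cholesterol synthesis (0.0964) and metallothioneins (0.162). For DC these were all lower and comprised the type I signature (0.626), cytokines (0.566), MHC class II (0.626) and class I (0.626), the IFN gamma response (0.636) and ATF4 targets (0.636). Once GC trends were removed, immediate early genes (0.0715) and metallothioneins (0.537) were not called for TEPA, nor ATF4 targets (0.0518) and MHC class I (0.0911) for DC. Adjusted over the list alone, 4 members of the type I signature and 1 of the IFN gamma response were lower in the TEPA interaction, and 0 members of the other lists here were called.

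Copper, which was added for 4 h, and TEPA, which binds copper and was given for 24 h, shared 29 called genes (9.06 expected, with p = 2.13e-08 by Fisher's exact test across genes). Of these 7 were higher in both, 9 lower in both, 8 higher with copper and lower with TEPA, and 5 the reverse, and no association of the directions was detected among these 29 (Fisher's exact test, p = 0.71). SLC30A1 (2.56 and -1.5), SLC7A11 (3.59 and -1.19) and IFRD1 (1.49 and -1.23) were among those higher with copper and lower with TEPA, while BDNF (0.71 and 0.68) rose in both (chosen after their values were seen). BDNF lost its TEPA call in 4 of 6 fits without 1 library (adjusted p up to 0.0945). With TEPA on top of IFN, copper shared 55 called genes (16.3 expected, p = 9.19e-16), 16 higher in both, 27 lower in both, 8 and 4 in opposite directions (Fisher's exact test of direction, p = 5.59e-05). Both genes called with DC rose with copper too. DC and TEPA shared 0 called genes in edgeR (0.0212 expected; 1 in DESeq2). They shared 4 with GC trends removed, 1 in the same direction and 3 in opposite ones, and 3 (1 and 2) with a replicate block in the libraries alone. The correlation of their fold changes across genes was 0.578. In 20 simulations without any effect the shared control libraries alone gave 0.492 (SD 0.017). The simulated libraries were drawn independently and without a GC trend. The real ones carry that trend and met the cutoff for pairing by number, so the excess is not assigned to treatment.

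The overlap of copper and TEPA was 0 in the libraries of each comparison alone, 88 in DESeq2 and 459 with GC trends removed. Of the 459, 263 moved in the same direction and 196 in opposite ones (Fisher's exact test of direction across genes, p = 0.00587). Without control library 1 at 4 h it was 54, without control library 1 or TEPA library 3 at 24 h 13, without TEPA library 1 14 and without control library 3 at 24 h 18. The 94 genes shared by TEPA without and with IFN became 241 in DESeq2, 806 with GC trends removed and 0 in the libraries alone. They fell to 44 without TEPA library 3, 46 without control library 1, 51 without control library 3 and 57 without TEPA library 1.

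The untreated controls at 24 h and 4 h differ in time and in whatever else set the 2 harvests apart, which the labels do not give. At 24 h the calcium-activated potassium channel KCNN3 (3.39, SE 0.34), PPP2R2C (4.01, SE 0.61), TMEM178B (2.55), TRIM67 (2.53) and MPPED2 (2.45) were higher. TNFRSF12A (-2.72, SE 0.42), the early growth response corepressor NAB2 (-2.38, SE 0.33), ATP1B2 (-1.88) and the VEGF receptor FLT1 (-1.72, SE 0.22) were lower. TNFRSF12A and NAB2 had -1.83 and -1.55 with GC trends removed. GOLGA8R (5.25) has near-identical copies and is uncertain. CD274 (-0.27, SE 0.32), STAT3 (-0.08), IRF1 (-0.41), EGFR (0.03), MT2A (-1.14), MT1X (-2.15), HMOX1 (-0.73), HSPA1A (0.49) and TFRC (0.15) were not called. MT1X (-1.92, adjusted p = 0.0363) and HSPA1A (1.05, adjusted p = 0.00438) were with GC trends removed. SLC31A1 had 0.03 (SE 0.09, adjusted p = 0.817), and with GC trends removed -0.11 (adjusted p = 0.0349; 0.0331 to 0.978 over the alternatives).

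Lists lower at 24 h were DNA replication (8 of 40; 14 adjusted over the list alone), immediate early genes (7 of 30; 9), cytosolic ribosomal proteins (1 of 30; 19), mesenchymal identity (4 of 23, such as vimentin VIM at -0.38; 4) and ribosome biogenesis (3 of 26; 3). Heat shock was higher (6 of 24; 7). None of the 6 passed with an estimated correlation (adjusted p = 0.535, 0.535, 0.559, 0.172, 0.0551 and 0.535). Immediate early genes (0.189) and mesenchymal identity (0.0548) were not called with GC trends removed. Of the remaining lists, SLC39A10 rose as 1 of 7 metallothioneins and MTF1 targets (0.62), ERAP1 as 1 of 21 MHC class I genes (0.45), PMP22 as 1 of 5 Schwann cell markers (0.46), and TNFSF4 among 15 checkpoint ligands (1.11). COL1A2 fell as 1 of 10 fibroblast and endothelium markers (-0.78). SLC39A10 and ERAP1 lost their calls in 4 and COL1A2 in 3 of 6 fits without 1 library (adjusted p up to 0.165, 0.115 and 0.0854). Each of these lists had the same count adjusted over the list alone, except the first (1 up, 2 down). CD276 fell (-0.53, adjusted p = 0.0397), but had 0.04 with GC trends removed and lost its call in 5 of 6 fits without 1 library (adjusted p up to 0.261). Of 36 IFN gamma response genes 5 rose and 2 fell (6 and 3 adjusted over the list alone), and 0 of 21 copper transport, 2 epithelium and 3 leukocyte genes were called. In edgeR 1420 genes differed, 864 higher and 556 lower at 24 h. The count was 1 with the 6 libraries alone, 7375 without control library 1 at 4 h, and 555 without control library 3 at 4 h. It was 3684 with GC trends removed, where the balance turned (1656 higher, 2028 lower).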

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

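The tests in this part were chosen only after the results were seen, except the interactions themselves, the test of a trend with expression level and the test of a single library.

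A difference between the TEPA effect with IFN and that without was found for 6 genes once GC trends were removed. Among these log2 differences were 1.29 for SLC7A11 (adjusted p = 0.0222 in edgeR), 1.1 for IFRD1 (0.00165), 0.42 for SLC39A10 (0.0222), 0.29 for NFYA (0.0374) and -0.64 for SAMD9 (0.0241). Without the correction the adjusted p was 1 for each of these genes, with differences of 1.32, 1.12, 0.43, 0.30 and -0.62. With it, the TEPA effects without and with IFN were -1.12 and 0.18 for SLC7A11 and -1.18 and -0.08 for IFRD1. They were 1.3 and 1.72 for SLC39A10, -0.29 and 0 for NFYA, and 0.03 and -0.61 for SAMD9. On top of IFN SLC7A11, IFRD1 and NFYA were not called (adjusted p = 0.51, 0.665 and 0.973 in edgeR). For 3 lists the difference passed camera with an estimated correlation (adjusted p = 0.0431 each) without a called member, with medians of -0.50 for the type I interferon signature, -0.13 for hypoxia and -0.13 for adrenergic identity, the last not called by camera with GC trends removed (adjusted p = 0.0941). The difference of the type I list also rests on the IFN libraries whose level is in question below. Regroupings of the 12 libraries decide nothing here, since the real grouping called 0 genes in either interaction and all 50 reach that. The highest other counts were 929 for TEPA and 4 for DC. Both came from the regrouping that swaps treated and untreated libraries on 1 side, which adds the effects of a chelator without and with IFN in place of their difference.

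Libraries of 1 group stood apart along a first within-group component with 64.9% of the within-group variance. A spline of each library against GC content removed 48.4% of that variance, and the Spearman correlation of the component's gene loadings with GC content was 0.86 across genes, which are not independent replicates. Transcript length removed 6.83%, which argues against length as the source. A trend with expression level removed 14.6%, which leaves it open in part. These values are consistent with a GC bias of library preparation or sequencing, and no biological explanation was tested.

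The p53 targets rose with TEPA with a median of 0.80. The median was 0.72 with GC trends removed, which argues against that bias as the whole source. The lowest median over 6 fits without 1 library was 0.67, which argues against a single library. With TEPA on top of IFN, in 6 other libraries, it was 0.66, and a p53 response to TEPA may be a candidate explanation. Harvest and plating order, which the labels do not give, stay open.

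The type I interferon signature was lower with TEPA on top of IFN, with a median of -0.36. With GC trends removed it was -0.32, which argues against that bias as the whole source. With DC on top of IFN, against the same 3 IFN libraries, it was also -0.32, and between the TEPA with IFN and the DC with IFN libraries it was 0.04. Two-sided exact permutation tests of the list score gave p = 0.3 for each chelator, where 3 against 3 cannot go below 0.1. An effect of both chelators and a high level in the shared IFN libraries cannot be told apart from these values, and the medians with TEPA and DC were -0.19 and -0.16 without IFN library 1, -0.23 and -0.30 without 2, and -0.50 and -0.47 without 3.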

How the results depend on the processing

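The GC correction, its combination with the replicate block, the block in the libraries of a comparison alone and the removal of both libraries numbered 1 at 4 h were chosen after seeing the data. Median-of-ratios factors and a filter at a mean of 1 CPM left all 15 main results the same, and limma-voom all 14 that it gives. For the counts this means within 1.5 times, and for CD274 with IFN, which is among them, that its call stayed. Of 265 calls of named genes 86 were lost in at least 1 fit without 1 library, and of 97 list calls 37. The GC correction ended 15 of 264 such calls of named genes and 19 of 97 list calls, and started 34 and 15. The cause was not tested for the values below, except that Bonferroni adjustment and the fold threshold are stricter by construction. The libraries alone leave fewer residual degrees of freedom. That does not account for all their counts, since the count rose there for IFN. With a further block, which leaves fewer still, it rose for copper and TEPA. Depth limits metallothioneins and genes at 0 counts in a control group, whose folds are bounds or carry wide counting intervals, and the SE of MT1X with TEPA was 1.07.

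With the libraries of a comparison alone, counts were 61 (59 higher, 2 lower) for copper, 1 for DC, 0 for TEPA, 6703 for IFN, 1 for DC on top of IFN, 121 for TEPA on top of IFN, 2 for TEPA against DC and 1 for the controls, with overlaps of 0 for copper and TEPA and 0 for TEPA without and with IFN. With the block in addition they were 2547, 6, 247, 7252, 0, 2777, 406 and 0, with 1 for the TEPA by IFN interaction and overlaps of 87, of 3 for DC and TEPA, and of 227.

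With the GC correction they were 3003, 7, 1181, 5616, 7, 1811, 1361 and 3684, with 6 for the TEPA by IFN interaction and overlaps of 459, 4 and 806. Of the called genes testable there, it called 752 of 816 for copper, 128 of 141 for TEPA, 2242 of 2634 for IFN, 237 of 261 for TEPA on top of IFN, 148 of 168 for TEPA against DC and 1147 of 1344 for the controls. In the controls the direction turned for SLC31A1 (-0.11) and CD276 (0.04). With the GC correction and the block the counts were 3219, 8, 1394, 6136, 8, 2054, 1581 and 4200, with 16 for the TEPA by IFN interaction, overlaps of 550, 4 and 934, and -0.11 for SLC31A1 and 0.07 for CD276.

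With the block alone counts were 4333 for IFN, 428 for TEPA on top of IFN, 287 for TEPA against DC, 2 for the TEPA by IFN interaction and 2254 for the controls, with overlaps of 60 for copper and TEPA and 155 for TEPA without and with IFN. Without both libraries numbered 1 at 4 h the controls had 8191 genes and copper and TEPA shared 51, while copper had 744, within 1.5 times.

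DESeq2 called 374 genes for TEPA, 6 for DC on top of IFN, 583 for TEPA on top of IFN, 434 for TEPA against DC, 2 for the DC by IFN interaction and 2510 for the controls, with overlaps of 88 for copper and TEPA, 1 for DC and TEPA and 241 for TEPA without and with IFN. Upper-quartile factors gave 255 for TEPA, 474 for TEPA on top of IFN and 298 for TEPA against DC, with overlaps of 65 and 166. Without the low-count filter these were 86, 183 and 123, with 15 and 50.

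With a log2 fold change of at least 1 in size, counts were 127 for copper, 1 for DC, 34 for TEPA, 948 for IFN, 1 for DC on top of IFN, 50 for TEPA on top of IFN, 42 for TEPA against DC and 263 for the controls. Bonferroni adjustment gave 144 for copper, 23 for TEPA, 514 for IFN, 28 for TEPA on top of IFN, 27 for TEPA against DC and 99 for the controls. With an estimated correlation 33 gene lists passed in place of 97 (21 higher, 12 lower), and fry kept 47 of the 97.

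Leaving out 1 library in turn gave 61 to 127 genes for TEPA, 1707 to 3636 for IFN, 124 to 251 for TEPA on top of IFN, 75 to 207 for TEPA against DC and 555 to 7375 for the controls. The lowest came without control library 1, IFN library 2, TEPA with IFN library 2, DC library 1 and 4 h control library 3, and the highest for the controls came without 4 h control library 1. For the controls, counts were also low without 24 h control library 1 (632) or 3 (613) and 4 h control library 2 (643). The overlap of copper and TEPA ran from 13 to 54 and that of TEPA without and with IFN from 44 to 96. Within 1.5 times stayed copper (660 to 1129), DC (2 to 2), DC on top of IFN (2 to 3) and the gene lists (81 to 109). The median of DNA replication genes with DC ran from -0.09 to 0.03, and the list turned to the higher side without control library 2.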

Other observations

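The tests in this part were chosen only after the results were seen, as were the genes of the next paragraph, while the lists and comparisons were not.

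With copper XBP1, a transcription factor of the unfolded protein response, rose by 1.89 (SE 0.10, n = 3) and HERPUD1 by 1.54 (SE 0.12), while the chaperone HSPA5 fell by 0.55 on the log2 scale and lost its call without copper library 3 (adjusted p = 0.0578 in edgeR). The list of ER chaperones was not called with copper (adjusted p = 0.252). The angiogenic factor VEGFA rose by 1.94 (SE 0.24) from 17.3 ± 4.96 to 66.3 ± 12.5 CPM, INSIG1 of sterol control fell by 1.07 (SE 0.21) and the iron exporter SLC40A1 fell by 0.97 (SE 0.18). With IFN the migration protein DCX (-1.45, SE 0.17), the neurofilament NEFM (-1.01, SE 0.14) and the monoamine transporter SLC18A2 (-1.41, SE 0.20) fell. The neuronal differentiation list had 2 members up and 8 down of 26 and was not called with IFN (adjusted p = 0.116). FAS rose with IFN as well (2.93, SE 0.24), and ACO1, which senses iron, fell (-1.37, SE 0.09). In the 24 h controls MAP2 (0.47, SE 0.10) and INSIG1 (1.12, SE 0.21) were higher than at 4 h.

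Lists without a call in any comparison include copper-dependent enzymes (12 tested), cuproptosis and lipoylation (14), zinc transport (14), PD-L1 regulators (29) and polyamine metabolism (19). With IFN, which had the most called members, these had 0 up and 2 down, 3 and 1, 0 and 1, 6 and 3, and 1 and 2. No mitochondrially encoded gene was among the genes tested. This does not show low levels, since such genes may be missing from the deposited counts. EPCAM of epithelium averaged 0.453 CPM and PTPRC of leukocytes 0.288 CPM over the 24 libraries, while COL3A1 (315 CPM) and PDGFRA (239 CPM), listed as fibroblast markers, are abundant in this line.

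A hypothesis is that TEPA lowers and copper raises the metal that MTF1, the metal-sensing transcription factor, responds to. Of the MTF1 list, the members with a count in the TEPA or 24 h control libraries, 6 in number, had opposite signs with copper and TEPA in 6 of 6 cases. SLC30A1 had 2.56 and -1.5, MT2A 5.28 and -1.37, and SLC39A10, which MTF1 lowers, -0.56 and 1.25. These signs do not decide the hypothesis, which was formed after some of them were seen. Of the 6 members SLC30A1 and MT1F were called with both treatments. SLC39A10 was too with GC trends removed (-0.50 with copper, adjusted p = 2.73e-07, and 1.3 with TEPA, 9.78e-13). Metallothioneins are near-identical and not independent. MT1E, MT1X and MT2A had adjusted p of 0.812, 0.609 and 0.572 with TEPA. Whether zinc or copper changed cannot be told from RNA.

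Other splits of the 6 libraries of a comparison were also fitted. With 10 splits of 3 against 3 they are too few for a share under 0.05. The real split called 2 genes for DC, 155 for TEPA, 2761 for IFN, 3 for DC on top of IFN, 279 for TEPA on top of IFN and 185 for TEPA against DC, and the highest other split 0 in each (1 of 10 as large, the real one). For copper the real split called 857 and the highest other 6546, with 3 of 10 as large, namely the real one and 2 that keep both libraries numbered 1 on 1 side. The 6546 came from control libraries 1 and 2 with copper library 1 and the 4858 from control library 1 with copper libraries 1 and 2, which points to a structure of the samples. Keeping both libraries numbered 1 together does not by itself give such counts, since the 2 other splits that do so called 0 genes. The split with 6546 set the 3 lowest GC differences (-1.32, -0.645 and 0.653) against 0.797, 1.34 and 1.38. That with 4858 traded 0.653 for 0.797. The 2 splits with 0 genes put 1.38 or 1.34 on the side of the low values. High counts thus went with a sorting of the libraries by the GC trend. The 3 other splits that part all 3 number pairs called 0 genes each. They mix copper and control libraries on both sides and are too few, so their 0 lends no weight to the 857. With a replicate block copper had 1100 genes. For the 24 h against the 4 h controls the real split called 1420 and the highest other 6463 (2 of 10 as large). The latter came from 24 h libraries 1 and 3 with 4 h library 1. Here too the 3 lowest GC differences (-0.962, -0.787 and -1.32) stood against -0.363, 0.653 and 1.38. The numbers do not pair these libraries, and with a block in these 6 alone 0 genes were called.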
